A study of Caenorhabditis elegans with 2 samples.

How the data were processed

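Chromatin immunoprecipitation followed by sequencing was done on whole L1 larvae of Caenorhabditis elegans, the first larval stage, of mixed sex. Per the labels, the strain carries an integrated transgene that expresses DPL-1 fused to GFP, TY1 and FLAG tags, together with an unc-119 rescue in an unc-119 mutant, and the tagged protein was the target of the precipitation. The series holds 2 samples, which the labels call biological replicates 1 and 2 of 1 group, so there was no comparison between groups and no replicate numbers to pair. The labels give a size range of 150 to 350 without a unit, and they name a possible control experiment, which was not analysed here. No read counts stand in the peak lists, so the depth of each library is unknown and no depth-based interval was given.

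Per the deposited file listing, the authors made a relaxed peak list for each replicate from that replicate's alignments and 1 control file, and a pooled relaxed list from the alignments of both replicates and the control file. Another kind of list, thresholded by the irreproducible discovery rate (IDR, a measure of how reproducible peak ranks are between replicates), was derived by the authors from the 3 relaxed lists, per the same listing. Each kind of list was deposited on the ce11 and the ce10 build. The aligner, the peak caller, the IDR threshold and their versions are not given in the sources used here. The deposited signal value of a peak is its strength as given by the authors' caller. The scale of that signal is not stated, so its values have no absolute meaning here. Signals were ranked and their log2 medians compared within a list, and they were correlated between the replicates' lists at matched peaks, but levels were not compared between lists. The deposited −log10 q values ran up to 3.73 in the IDR list, and they were not used for ranking. The summit of a peak was taken as its deposited start plus its deposited offset, and coordinates are given 1-based on ce11. Neither set of coordinates was converted, and ce10 lists entered only comparisons that need no gene model.

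The relaxed lists of both replicates hold exactly 30000 peaks each. The IDR list on ce11 held 2797 peaks, and these were the 2797 strongest peaks of the pooled relaxed list of 23883 peaks. The IDR peaks thus carry the values of the pooled list, not of single replicates. For every result that needed an error between replicates, the 2797 strongest peaks of each replicate's own list were analysed in the same way, and the mean ± SD of the resulting 2 values is given. Intervals in brackets after a share are exact 95% Clopper-Pearson intervals over peaks or genes, which cover counting error only.

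Genes were the 19973 protein-coding genes on the 6 nuclear chromosomes of Ensembl release 115 for WBcel235, whose coordinates are those of ce11. A gene was called bound when a summit lay from 1000 bp upstream to 200 bp downstream of the 5' end of any of its protein-coding transcripts. A summit in the windows of several genes was counted for each of them, as happened for 820 peaks, so neighbouring genes are not independent. Annotated 5' ends of trans-spliced transcripts can lie downstream of the start of transcription. Members of families with near-identical copies, such as the histone genes, are uncertain because it is not stated how reads that map to several places were treated.

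The gene lists, tests and alternatives were fixed before the data were examined, except where the text says otherwise. The 19 lists cover DNA replication, cell-cycle control, chromosome segregation and centrosome, DNA repair and checkpoint, meiotic prophase, germline and P granule, the DREAM complex, other synMuv chromatin genes, small RNA pathways, muscle structure, intestine, neuronal genes (broadly neuronal genes together with genes of particular neuron types), core histones, cytoplasmic ribosomal proteins, cuticle collagens, neuropeptides, chemoreceptors, nuclear hormone receptors, and the F-box and MATH-domain family. Of 588 genes asked for by name, 16 were not matched. Lists overlap in a few genes, and dpl-1 itself stands in several. The bound share of a list was compared with that of all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 19 lists. The threshold was an adjusted p of 0.05. The genes named were dpl-1 and unc-119, the genes of the 20 strongest IDR peaks, for each list that passed the 5 bound members with the strongest peaks and up to 3 members without a peak in alphabetical order, all DREAM members, and for other lists the 2 bound members with the strongest peaks. Neighbours named as sharing a peak were chosen after their values were seen, and not every shared peak has its neighbour named. Any other name too was chosen after its values were seen, which the text says where it occurs.

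Summits were called shared when they lay within 100 bp of each other. Overlaps and promoter shares were compared with 1000 circular shifts of the peaks within each chromosome, in a one-sided test for which 0.001 is the smallest p possible. Chromosome shares were tested with a two-sided exact binomial test. Motifs were searched on both strands within 100 bp of the summit and in windows of the same size centred 500 bp to either side. The motifs were TTSSCGC, the site of E2F and DP proteins, TTYGAA, the cell-cycle homology region (CHR) bound by LIN-54, and CGCSSTT, the E2F motif in reversed order, as a control of the same base composition. Summit and lower flank were compared with a two-sided exact McNemar test. Medians of log2 signal were compared with a two-sided permutation test of 100000 resamples, for which 1e-05 is the smallest p possible. Lists with at least 5 bound members entered the signal test. The region of a gene was taken as 20 kb to either side of its midpoint.

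Alternatives covered the promoter window, assignment of each peak to the nearest gene only, leaving out 3613 genes that begin within 500 bp downstream of a gene on the same strand and are probably downstream in operons, stronger peaks, peaks among the strongest of both replicates, each replicate left out, other backgrounds, other motif windows and definitions, other overlap rules and the ce10 lists. Counts of shared peaks, motif shares per list, backgrounds with matched GC content, added gene families and non-coding genes were chosen after the data had been seen. The tests were checked on simulated data. For the bound share of gene lists, simulated over 19973 genes, 99.0% of lists of planted excess and 3.00% of random lists passed the adjusted threshold. Genes were drawn as bound independently there, so that rate does not cover neighbouring genes that share a peak. For the motif share, all planted motifs in 2000 simulated windows were found, which checks the search and not the test. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.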

Results

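DPL-1 is the C. elegans DP protein, the dimerization partner of E2F transcription factors and a member of the DREAM complex, which represses cell-cycle genes. Sites occupied by GFP-tagged DPL-1 were mapped in whole L1 larvae in 2 biological replicates. The IDR-thresholded list of the experiment held 2797 peaks on ce11, with a median signal of 71.5 and a range from 30.3 to 2461 in the units of the authors' caller. The relaxed lists held 30000 peaks in each replicate. Sequencing depth is unknown from these lists. The questions addressed were where tagged DPL-1 sits in the genome, at which genes, and with which sequence motifs.

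The strongest sites were the same in both replicates. The promoter peak of rpl-3, which encodes a protein of the large ribosomal subunit, ranked first in the IDR list and in each replicate, followed in each of these lists by cdc-48.1, which encodes an AAA ATPase, and then by rpl-35. All of the 20 strongest IDR peaks ranked 32 or better in each replicate. Among the 2797 strongest peaks of replicate 1, 2162 (77.3%, 75.7 to 78.8) had a summit of a top peak of replicate 2 within 100 bp, against a median of 0.644% and a maximum of 1.18% over circular shifts (circular permutation test, p = 0.001, the smallest the 1000 shifts can give). Of the IDR peaks, 2509 were matched in the top list of replicate 1 and 2397 in that of replicate 2, and 2683 (95.9%) were matched in both full lists. Across these matched peaks, which are not independent replicates, the signals of the replicates had a Spearman rho of 0.846 and a Pearson r of 0.893 on the log2 scale. The IDR peaks were chosen from the pooled data of both replicates, so part of this matching and correlation is built in. Between the replicates' own top lists, the overlap was 85.6% with shorter lists and 52.8% with lists 2 times as long. The deposited ce10 list held 2794 peaks, and 2775 peaks had the same chromosome, width, summit offset and signal (to 2 significant digits) in both builds.

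**Figure D1:**
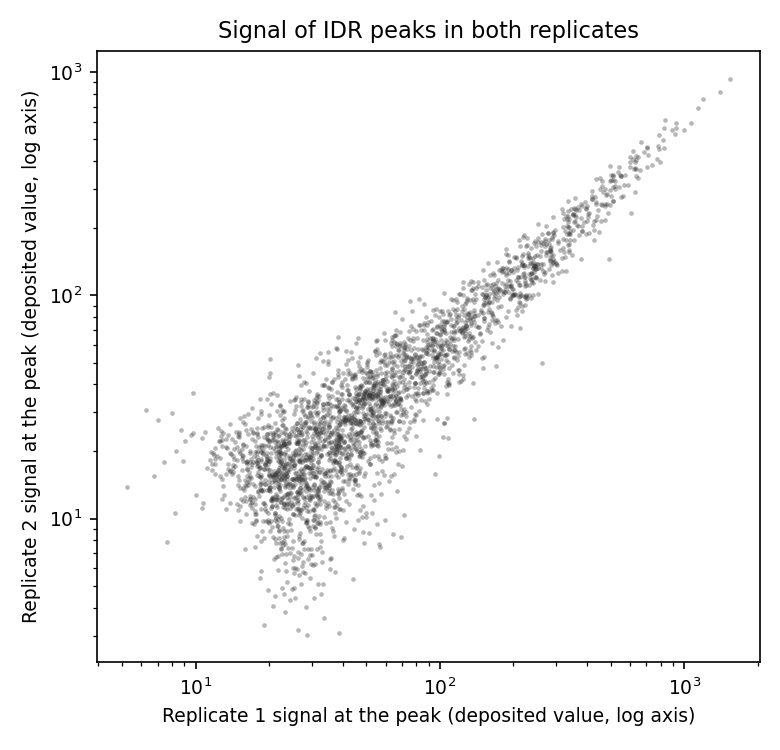
Signal of each IDR peak in replicate 1 (x axis) and replicate 2 (y axis), as deposited, on log axes, for the 2683 peaks matched in both full lists; each point is 1 peak. The points follow 1 diagonal (Spearman rho 0.846), with more scatter at low signal.

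Of the 20 strongest peaks, 17 lay in promoter windows. After rpl-3 (summit III:3867561, 293 bp upstream of the 5' end, signal 2461), cdc-48.1 (II:10563569, 162 bp upstream, signal 2202) and rpl-35 (III:7854679, 455 bp upstream, signal 1947) came a peak shared by tasp-1 and K01G5.10 (III:10759248, signal 1833). The peak between citk-2 and F59A6.11 had a signal of 1647, that of dld-1, which encodes dihydrolipoamide dehydrogenase, 1536, and that of sec-61.G and F32D8.13 1509. A peak of signal 1482 lay between rbd-1 and T23F6.3. The E2F gene efl-1 itself carried the peak of rank 9 (V:16965694-16966004, signal 1443), which lies in the intergenic region 171 bp upstream of efl-1 and 968 bp upstream of fbxa-90. The list went on with eelo-2 (signal 1442), cox-5A, a cytochrome c oxidase subunit gene (1436), the alpha-tubulin gene tba-2 (1381), F48A11.4 (1318), ddp-1 with ttc-7 (1283), Y53F4B.9 with Y53F4B.11 (1245), the RNA polymerase II subunit gene rpb-11 with W01G7.4 (1186) and pdhk-2 (1181). The remaining strong peaks lay outside promoter windows. A peak on chromosome I (16861 to 17171, signal 1242) was intergenic and 1913 bp downstream of the nearest 5' end, that of nlp-40. A pair of peaks with signals of 1211 and 1200 lay in an intron and in the 3' UTR of egl-5, a Hox gene, and shared the deposited interval III:7814331-7816992. That interval spanned 2662 bp, against a median width of 316 bp, and why it was so wide was not tested. An E2F motif was found within 100 bp of the summit in 9 of the 20 peaks.

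Peaks lay mainly just upstream of genes. A summit fell in a promoter window in 2094 of 2797 peaks (74.9%, 73.2 to 76.5), against a median of 26.1% and a maximum of 28.6% over circular shifts (circular permutation test, p = 0.001, the smallest possible). The strongest peaks of the replicates gave 74.1% ± 1.16 (SD, n = 2). The median summit lay 177 bp upstream of the nearest 5' end, and 41.0% of summits lay within 200 bp of it. By annotation, 77.0% of summits were intergenic against 35.5% after shifting, 4.43% lay in 5' UTRs against 1.75%, and 16.3% in introns against 34.5%. Coding and other exons held 0.930% of summits against 24.6% after shifting, and 3' UTRs 1.32% against 3.65%. Promoter windows held 57.7% of the peaks in the lowest quintile of signal and 95.3% of those in the highest.

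Chromosomes I and III carried the most peaks for their length and the X chromosome the fewest. Peak density was 44.3 per Mb on chromosome III (replicates 43.9 ± 1.49, SD, n = 2), 39.5 on I (39.2 ± 0.704), 31.4 on II (31.2 ± 0.509), 26.5 on IV (26.2 ± 0.0404), 18.7 on V (19.3 ± 0.270) and 14.3 on X (14.8 ± 1.36). The X held 254 peaks, 9.08% (8.04 to 10.2) of all, while it makes up 17.7% of the nuclear genome length, a ratio of 0.514 (two-sided exact binomial test, adjusted p = 4.4e-37 over 6 chromosomes). Among the peaks above the median signal the X held 5.65%. Chromosome V was also below its length share (ratio 0.672, exact binomial test, adjusted p = 2.4e-20), I and III were above it (ratios 1.42 and 1.59, adjusted p = 1.4e-18 and 1.0e-30), II was slightly above (1.13, adjusted p = 0.0063), and IV did not pass the test (0.951, adjusted p = 0.24). Relative to the chromosomes' shares of protein-coding genes, the lowest ratio of the 6 was that of V (0.561, unadjusted exact binomial p = 4.3e-46), followed by X (0.664, p = 1.1e-13), and neither II (0.994, p = 0.90) nor IV (1.01, p = 0.82) passed, while I and III were above (1.48 and 1.65, p = 9.1e-23 and 7.3e-36).

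**Figure D2:**
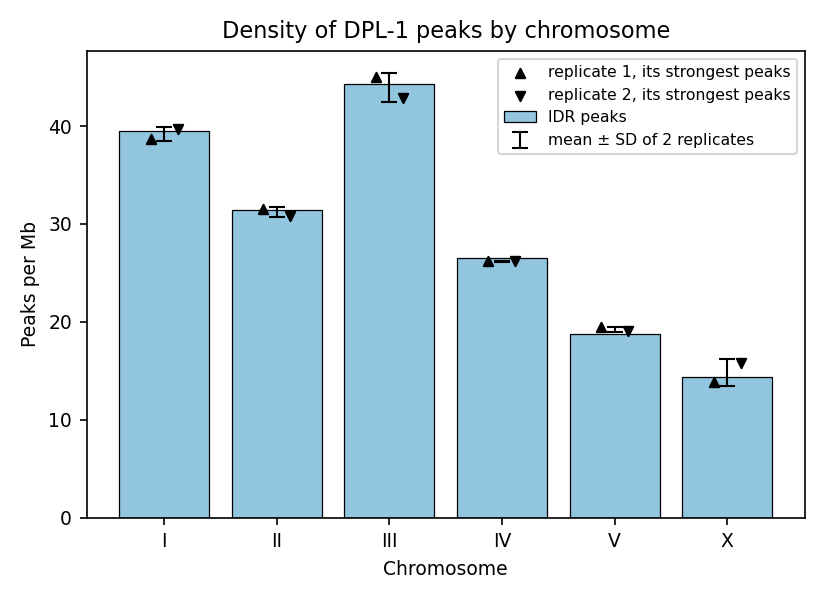
Peaks per Mb (y axis) on each chromosome (x axis); bars show the IDR list, triangles the strongest 2797 peaks of each replicate, and error bars the mean ± SD of the 2 replicates. Density runs from 44.3 per Mb on chromosome III down to 14.3 on X.

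At the level of genes, 2864 of 19973 protein-coding genes (14.3%) had a summit in their promoter window. Of the 19 gene lists, 8 had a higher bound share than other genes, 6 a lower one and 5 did not pass the test. Many promoter peaks lie between neighbouring genes, and the number of bound members whose peaks all lay in the window of another gene too was 25 of 40 for DNA replication, 41 of 56 for segregation, 49 of 72 for ribosomal proteins, 21 of 34 for DNA repair and 14 of 23 for cell-cycle control.

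The genes that copy and divide chromosomes were bound in most cases. Of 47 DNA replication genes, 40 were bound (85.1%, 71.7 to 93.8; replicates 86.2% ± 1.5, SD, n = 2), against 14.2% of other genes (odds ratio 34.6, Fisher's exact test, adjusted p = 1.5e-26). The strongest peaks were at top-2, the topoisomerase II gene (signal 1061, a peak shared with the nuclear pore gene npp-3), and pcn-1, which encodes PCNA (1008). Next came orc-5, of the origin recognition complex (691, shared with cyb-1), and tim-1, the Timeless homologue (657, shared with Y75B8A.23). The clamp loader gene rfc-4 followed (632, shared with the translation elongation factor gene eef-1A.1). No peak lay at ctf-18, orc-2 or pole-2. Of 66 chromosome segregation and centrosome genes, 56 were bound (84.8%, 73.9 to 92.5; replicates 82.6% ± 3.21, SD, n = 2; odds ratio 34.1, Fisher's exact test, adjusted p = 1.1e-36). Leading members were the kinetochore genes kbp-4 (signal 851) and knl-3 (762) and the condensin genes kle-2 (653) and hcp-6 (473). Another was sas-4 (594), which acts in centriole assembly. The peaks of kbp-4, knl-3, kle-2, hcp-6 and sas-4 all lay in the window of another gene too. The genes cpar-1, dpy-28 and gip-1 had no peak. Of these, dpy-28 begins within 500 bp downstream of tasp-1 on the same strand, as in operons, and tasp-1 carried a peak (signal 1833). Without genes lying close downstream of another gene on the same strand, the share was 91.7% for replication and 89.3% for segregation genes (Fisher's exact test, adjusted p = 2.0e-23 and 7.6e-34). With each peak assigned only to the nearest gene, the share was 53.0% for segregation genes and 70.2% for replication genes, and both passed (Fisher's exact test, adjusted p = 1.2e-17 and 7.1e-22).

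Cell-cycle control and DNA repair genes were bound more often than other genes. Of 49 cell-cycle control genes 23 were bound (46.9%, 32.5 to 61.7; odds ratio 5.32, Fisher's exact test, adjusted p = 1.3e-07), and each replicate also gave 23. They were led by efl-1, the inhibitory kinase gene wee-1.3 (signal 1120), the cyclin B gene cyb-1 (691, a peak it shares with orc-5), the separase gene sep-1 (502) and the securin gene ify-1 (495, shared with rpl-22). The anaphase-promoting complex genes apc-10 and apc-2 and the phosphatase gene cdc-25.1 had no peak. Of 65 DNA repair and checkpoint genes 34 were bound (52.3%, 39.5 to 64.9; replicates 49.2% ± 4.35, SD, n = 2; odds ratio 6.62, Fisher's exact test, adjusted p = 2.3e-12). The strongest were hpr-17 (signal 990), polh-1 (910), the nuclease gene fan-1 (638), the BRCA1 homologue brc-1 (519) and mrt-2 (506), whereas apn-1, brc-2 and the p53 homologue cep-1 had none. Without genes lying close downstream of another gene on the same strand, as in operons, the DNA repair share was 73.7% (Fisher's exact test, adjusted p = 4.4e-15).

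Most genes of the complex to which DPL-1 belongs were themselves bound. Peaks lay at 6 of the 8 DREAM genes (75.0%, 34.9 to 96.8; odds ratio 18, Fisher's exact test, adjusted p = 0.00030). Besides efl-1 these were lin-54 (IV:13240678, signal 781, shared with the ribosomal protein gene rpl-12), lin-9 (III:8904287, signal 634), lin-53 (I:9620003, signal 547), lin-35, the worm retinoblastoma homologue (I:5807542, signal 358), and lin-52 (III:9825688, signal 40.1). The genes lin-37 and dpl-1 had no peak. Of the 6 bound DREAM genes, 5 had peaks that lay in another gene's window too, all but lin-9. With each peak assigned only to the nearest gene, the DREAM share fell to 37.5% and no longer passed (Fisher's exact test, adjusted p = 0.061). Among 36 other synMuv chromatin genes, which act with DREAM in vulval development, 18 were bound (50%, 32.9 to 67.1; replicates 50% ± 3.93, SD, n = 2; odds ratio 6.0, Fisher's exact test, adjusted p = 1.0e-06). The strongest were the SUMO gene smo-1 (signal 322), the acetyltransferase gene mys-1 (286), mcd-1 (201), trr-1 (200) and lin-36 (174), and ark-1, arle-14 and dpl-1 had no peak. With a promoter window of 500 bp upstream the synMuv share was 33.3% (Fisher's exact test, adjusted p = 0.0011). The synMuv list holds dpl-1 too, which is a DREAM gene, and whether every member acts on chromatin was not checked.

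Most cytoplasmic ribosomal protein genes were bound. Of 81 genes 72 were bound (88.9%, 80 to 94.8; replicates 88.3% ± 0.873, SD, n = 2; odds ratio 49, Fisher's exact test, adjusted p = 5.6e-50). After rpl-3 and rpl-35 the strongest were rpl-24.2 (signal 1052), rps-22 (910, a peak shared with polh-1) and rps-12 (896). No peak lay at rla-1, rpl-11.1 or rpl-16. With each peak assigned only to the nearest gene the ribosomal share was 51.9% (Fisher's exact test, adjusted p = 2.0e-20). Small RNA pathway genes were bound in 17 of 52 cases (32.7%, 20.3 to 47.1; replicates 32.7% ± 2.72, SD, n = 2; odds ratio 2.91, Fisher's exact test, adjusted p = 0.0014), led by rde-2 (signal 854), pash-1 (841), mut-15 (269), rde-4 (247) and nrde-2 (174), and the Argonaute genes alg-1, alg-3 and alg-4 had none. The small RNA share was 21.2% with the peaks above the median signal (Fisher's exact test, adjusted p = 0.0076), and with nearest genes only it was 17.3% and did not pass (adjusted p = 0.14).

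Of the other lists, 5 did not pass the test in either direction. Meiotic prophase genes were bound in 8 of 39 cases (20.5%, 9.30 to 36.5; Fisher's exact test, adjusted p = 0.30), with the strongest peaks at rec-1 (signal 251) and pch-2 (229). Germline and P granule genes were bound in 13 of 67 cases (19.4%, 10.8 to 30.9; Fisher's exact test, adjusted p = 0.28), with mes-2, a Polycomb group gene (signal 852), and the DEAD-box helicase gene cgh-1 (616) in front. Core histone genes, many of them in near-identical copies, were bound in 12 of 72 cases (16.7%, 8.92 to 27.3; replicates 15.3% ± 5.89, SD, n = 2; Fisher's exact test, adjusted p = 0.61), with his-37 (signal 237) and his-67 (147) strongest. Genes of the neuronal list, set up to hold both broadly neuronal genes and genes of particular neuron types, were bound in 9 of 48 cases (18.8%, 8.95 to 32.6; replicates 15.6% ± 4.42, SD, n = 2; Fisher's exact test, adjusted p = 0.43). Its strongest peaks were at ric-19 (signal 585, shared with pmlr-1) and tbb-1 (264, shared with rib-2). Whether each member of that list is particular to neurons was not tested. Muscle structure genes were bound in 4 of 47 cases (8.51%, 2.37 to 20.4; Fisher's exact test, adjusted p = 0.34), among them act-2 (437) and unc-45 (410). With nearest genes only the shares of the meiotic and germline lists were 10.3% and 10.4%, and with the peaks above the median signal those of histone, neuronal and muscle genes were 4.17%, 6.25% and 4.26%.

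Several large gene families and the intestinal genes were bound less often than other genes. The lowest share of the 19 lists was that of the chemoreceptor family, with 7 of 1309 genes bound (0.535%, 0.215 to 1.1; odds ratio 0.0297, Fisher's exact test, adjusted p = 1.4e-77). The chemoreceptor genes with a peak were led by srh-16 (signal 830), sri-5 (783), srr-10 (452), srd-4 (303) and srh-89 (68.3), all of them peaks shared with a neighbouring gene, and sra-1, sra-10 and sra-11 had none. Neuropeptide genes were bound in 3 of 140 cases (2.14%, odds ratio 0.130, Fisher's exact test, adjusted p = 3.0e-06), which were ins-39, nlp-4 and nlp-24, while flp-1, flp-10 and flp-11 had no peak. Cuticle collagens gave 6 of 174 (3.45%, odds ratio 0.212, Fisher's exact test, adjusted p = 5.9e-06), with col-38 (signal 694, shared with rpl-5), col-2 (320, shared with the kinetochore gene ndc-80), col-71 (106), col-8 (85.7) and col-103 (65.3) bound and bli-1, bli-2 and col-10 not. Nuclear hormone receptors gave 14 of 269 (5.2%, odds ratio 0.325, Fisher's exact test, adjusted p = 4.9e-06), with nhr-47 (signal 193), nhr-142, nhr-85, nhr-49 and nhr-256 in front and nhr-10, nhr-100 and nhr-101 without a peak. The F-box and MATH-domain family gave 21 of 395 (5.32%, odds ratio 0.331, Fisher's exact test, adjusted p = 3.4e-08), led by fbxa-90, which shares the efl-1 peak, fbxb-88 (signal 587), fbxb-85 (431), bath-42 (415) and fbxc-23 (380, shared with csc-1), and bath-1, bath-10 and bath-13 had none. Among 48 intestinal genes only erm-1 was bound (2.08%, 0.0527 to 11.1; odds ratio 0.127, Fisher's exact test, adjusted p = 0.015), and act-5, asp-1 and asp-3 were not. The col-103 peak had no summit within 100 bp in the full list of replicate 1. With the nearest gene only the collagen share was 1.15%. The 5 lower lists other than the intestinal one kept their call with the nearest gene only and with the peaks above the median signal. Their shares moved, for example to 0.229% and 0.306% for chemoreceptors and to 4.09% and 1.49% for nuclear hormone receptors. The intestinal call was lost in Fisher's exact test with a promoter window of 500 bp upstream (adjusted p = 0.055), with the peaks above the median signal (adjusted p = 0.16) and with the nearest gene only (adjusted p = 0.13).

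**Figure D3:**
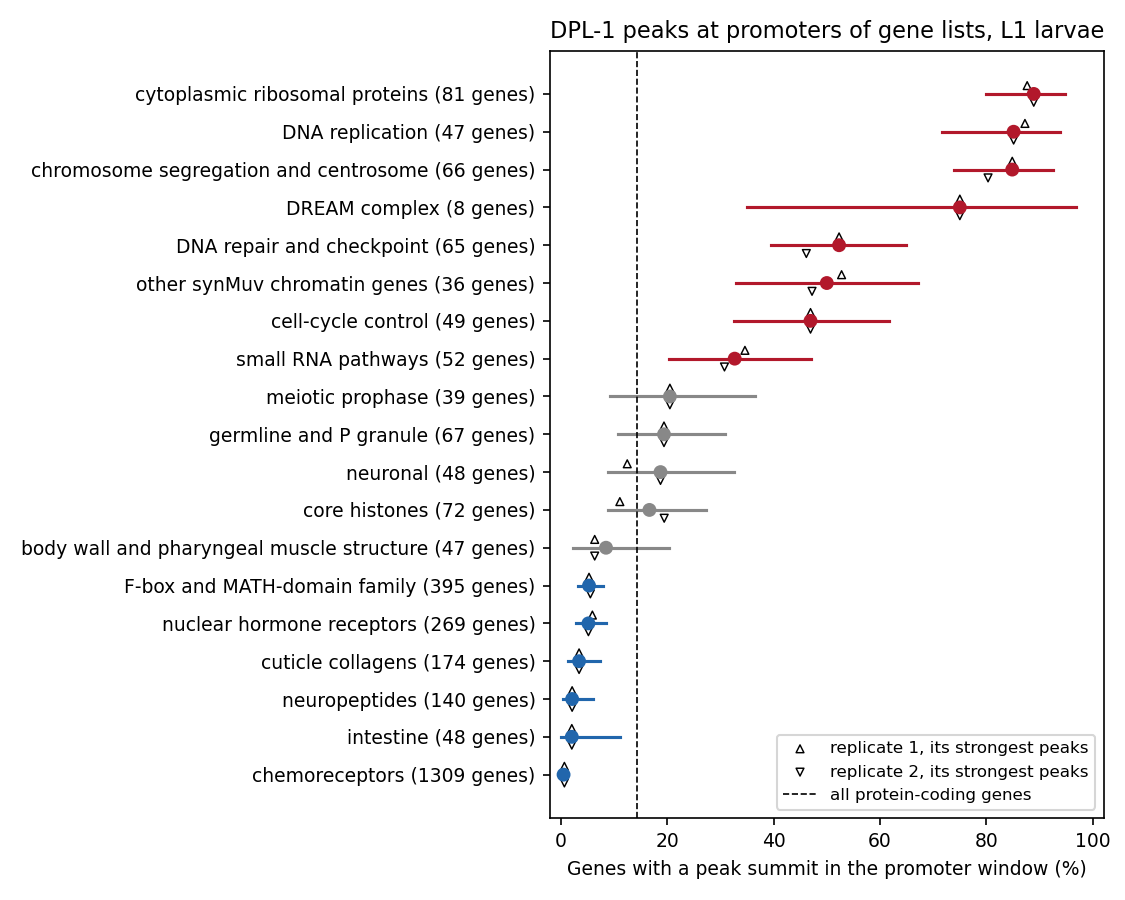
Share of genes with a peak summit in the promoter window (x axis, %) for the 19 gene lists (y axis); filled points with lines give the IDR list with exact 95% intervals, coloured red (higher), blue (lower) or grey (not passing), open triangles each replicate, and the dashed line the 14.3% of all protein-coding genes. Ribosomal protein, DNA replication and chromosome segregation genes lie above 80%, and chemoreceptors at 0.535%.

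Peaks at bound replication, segregation, DREAM and ribosomal protein genes were also stronger than those at other bound genes. The median signal at bound DNA replication genes was 290 against 94.0 at other bound genes, a log2 difference of 1.62 (permutation test, adjusted p = 0.00016 over 16 lists). The log2 difference was 2.63 for DREAM genes (median 589, permutation test, adjusted p = 0.0018), 0.98 for segregation genes (median 186, adjusted p = 0.0010) and 0.91 for ribosomal protein genes (median 173, adjusted p = 0.0010). The other 12 lists did not pass, among them DNA repair (0.73, permutation test, adjusted p = 0.060) and the few bound chemoreceptors (1.67, adjusted p = 0.060). For chemoreceptors the log2 difference was -0.27 in replicate 2 alone and -0.52 in replicate 1 alone. The DREAM difference rests on 6 bound genes, and the peaks of 5 of them also lay in another gene's window. With the nearest gene only, fewer than 5 DREAM genes stayed bound, so the DREAM signal was not tested there.

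The E2F motif was concentrated at summits. It occurred within 100 bp of the summit in 646 peaks (23.1%, 21.5 to 24.7; replicates 22.5% ± 0.0506, SD, n = 2) against 6.65% and 7.15% of the lower and upper flank windows, a ratio of 3.35 to the mean of the flanks (exact McNemar test, p = 1.8e-69). The same motif in reversed order was less frequent but enriched by nearly the same ratio, at 12.2% of summits (11 to 13.4) against 3.36% and 4.15% of the lower and upper flanks (ratio 3.24 to their mean, exact McNemar p = 9.7e-36). The CHR motif was found at 52.1% of summits (50.2 to 53.9) and at 52.2% and 50.8% of the lower and upper flanks, which did not pass the test (exact McNemar p = 0.96). Its direction depended on the peaks and the motif. The share was above the flank in the peaks above the median signal (60.7%, exact McNemar p = 1.5e-09) and in promoter peaks (56.6%, exact McNemar p = 0.00038). For a stricter motif it was below the flank (42.4%, exact McNemar p = 0.033). Against unbound promoters at the same distance, 56.6% of 2058 promoter peaks stood against 53.7% (Fisher's exact test, p = 0.064). With matched GC content, a background chosen after the data had been seen, it stood against 41.9% (Fisher's exact test, p = 4.0e-21).

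Peaks with an E2F motif were stronger, with a median signal of 97.3 against 64.4 without it, a log2 difference of 0.60 (permutation p = 1e-05, the smallest the resamples can give). The share of peaks with the motif was 14.6% (11.8 to 17.8) in the lowest quintile of signal and 38.1% (34.1 to 42.3) in the highest. The share with the reversed motif was 10.7% in the lowest quintile and 19.3% in the highest.

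The E2F motif was more frequent at the peaks of 2 of 16 lists than at other promoter peaks, in a comparison chosen after the data had been seen. It was found in 28 of 42 peaks at DNA replication promoters (66.7%, 50.5 to 80.4) against 23.2% of other promoter peaks (Fisher's exact test, adjusted p = 6.7e-08), among them top-2, pcn-1, orc-5 and tim-1. At chromosome segregation promoters it was found in 33 of 57 peaks (57.9%, 44.1 to 70.9; Fisher's exact test, adjusted p = 2.5e-07), among them kbp-4, knl-3 and sas-4. At cell-cycle control and DNA repair promoters the share was 38.5% and 37.1%, which did not pass (Fisher's exact test, adjusted p = 0.21 and 0.20). At ribosomal protein promoters 8 of 69 peaks had the motif (11.6%, 5.14 to 21.6) against 24.5% of other promoter peaks, which did not pass the correction in Fisher's exact test (adjusted p = 0.075) nor with a stricter motif (adjusted p = 0.13), but passed with windows of 50 bp (adjusted p = 0.022) and 250 bp (adjusted p = 0.024). DREAM promoters, with the motif in 4 of 6 peaks (Fisher's exact test, adjusted p = 0.10), passed with 250 bp (adjusted p = 0.035) and the stricter motif (adjusted p = 0.014) but had 16.7%, below other promoter peaks, with 50 bp (adjusted p = 1.0). Other synMuv promoters, with 9 of 19 (Fisher's exact test, adjusted p = 0.10), passed with 250 bp (adjusted p = 0.035) and not with 50 bp (adjusted p = 0.46) or the stricter motif (adjusted p = 0.14).

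**Figure D4:**
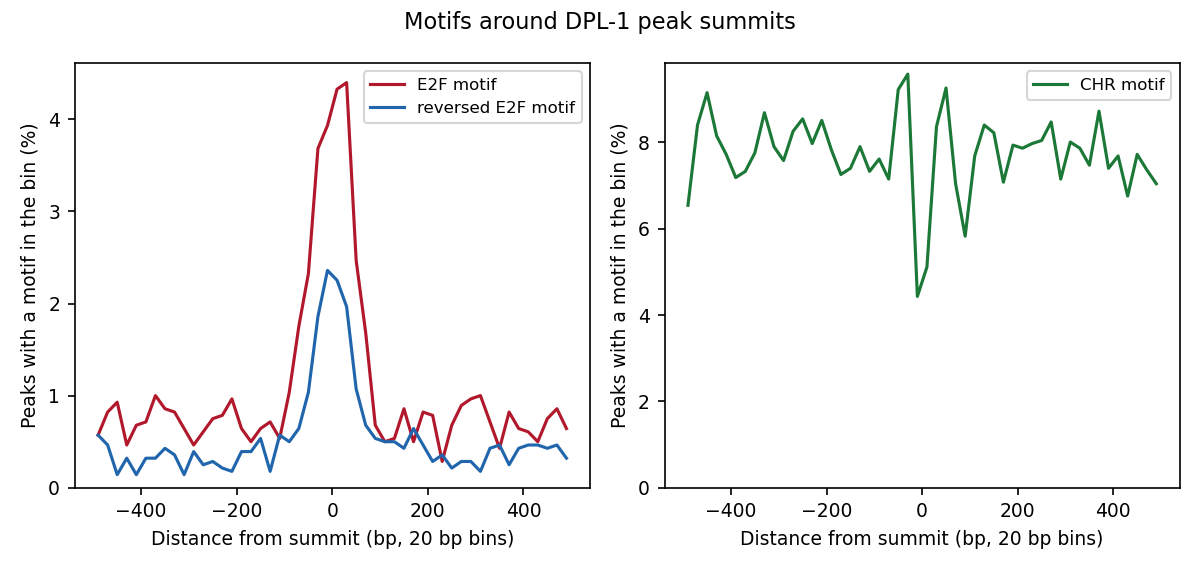
Share of IDR peaks with a motif in bins of 20 bp (y axis, %) against the distance from the summit (x axis, bp), for the E2F and reversed E2F motifs (left) and the CHR motif (right). The E2F motif peaks at 4.40% and the reversed motif at 2.36% near the summit, while the CHR motif dips to 4.43% just beside it.

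The loci present in the transgene were examined because the strain carries additional copies of dpl-1 and unc-119. The dpl-1 gene (II:9169910-9172565, plus strand) had no peak within 20 kb of its midpoint in the IDR list, the pooled relaxed list or either replicate's list of 30000 peaks. Such windows around protein-coding genes held a median of 12 peaks in each replicate, and 82 of 19973 genes in replicate 1 and 71 in replicate 2 had as few as dpl-1. The mean of these shares, 0.383% of genes, was 1.55% within 10 kb and 2.33% within 40 kb. Within 40 kb, 10 and 6 peaks lay near dpl-1 in replicates 1 and 2, and the shares were 3.99% and 0.681%. The peak-free stretch ran from II:9146420 to II:9200145 in replicate 1 (53.7 kb, the 9th longest of 29994 gaps between summits) and from II:9138710 to II:9201315 in replicate 2 (62.6 kb, the 4th longest). The region of unc-119 (III:10902641-10908935, plus strand) held 16 peaks in each replicate and 1 IDR peak, and 84.5% and 83.4% of genes had as few or fewer in replicates 1 and 2.

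**Figure D5:**
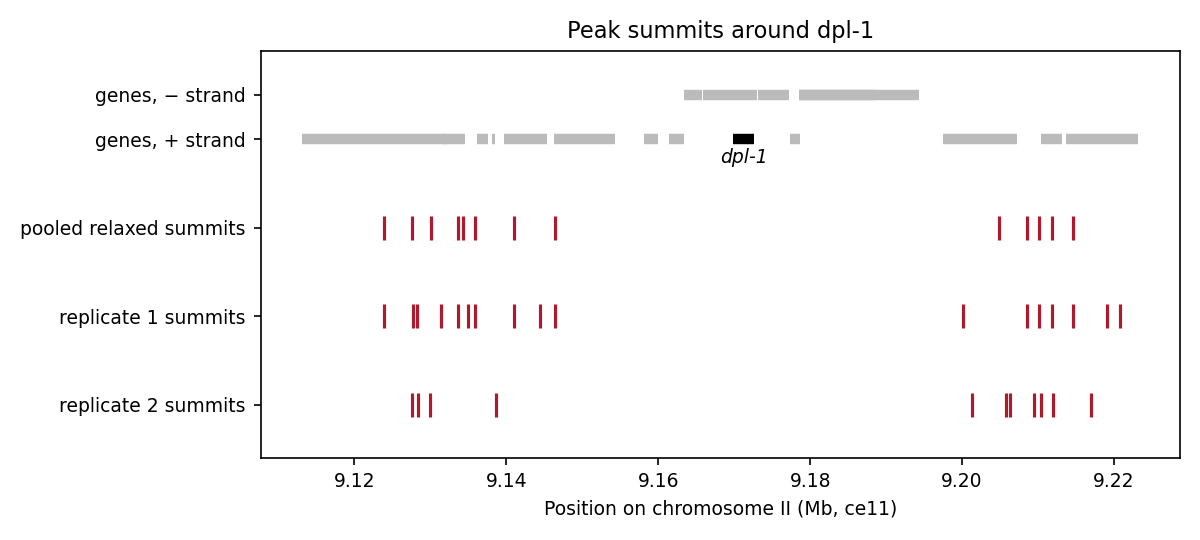
Peak summits of the pooled relaxed list and of each replicate (red ticks) and protein-coding genes by strand (grey bars, dpl-1 in black) along chromosome II (x axis, Mb, ce11). No summit lies in the 53.7 kb of replicate 1 or the 62.6 kb of replicate 2 that contain dpl-1.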

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

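The tests in this part were chosen after the data had been seen. A motif signal stood out in peaks of the pooled relaxed list that the motif comparisons did not use. The 2797 peaks that rank just below the IDR list had an E2F motif near the summit in 277 cases (9.90%, 8.82 to 11.1), against 6.97% of the lower flanks, a ratio of 1.42 (exact McNemar p = 6.5e-05). The reversed motif had a ratio of 1.56 in these peaks (exact McNemar p = 0.00041). The 2797 weakest peaks had the E2F motif in 5.68% of cases against 6.40% of flanks (exact McNemar p = 0.28). No biological explanation was tested.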

How the results depend on the processing

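Of 284 values recomputed for the results other than the E2F shares per list, 255 kept their direction and side of the threshold or stayed within a set range. That range was a spread, or for the peak count a fixed ratio. Of 48 values recomputed for the E2F shares per list, 36 kept their direction and side of the threshold and 7 changed direction. The other 5 came to pass the threshold and are given with the motif results. The exceptions follow, and the cause was not tested. Windows with matched GC content and the E2F shares per list were chosen after the data had been seen. The Spearman correlation of signals between replicates was 0.881 both with the peaks above the median signal and with summits within 50 bp. With the nearest gene only, the bound share was 37.5% for DREAM genes and 17.3% for small RNA pathways, which no longer passed, and 9.72% for core histones. The intestinal share stayed at 2.08% but did not pass with the nearest gene, the peaks above the median signal or a window of 500 bp upstream. Peaks above the median signal gave 6.25% for neuronal genes and 4.17% for core histones, and peaks among the strongest of both replicates 11.1% for core histones, below other genes though not past the test in either direction. Leaving out a replicate gave 12.5% to 18.8% for neuronal genes, 11.1% to 19.4% for core histones and 50.9% to 53.8% for the CHR motif.

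The CHR motif lay above its flank at 60.7% (peaks above the median signal), 55.3% (strongest of both replicates) and 56.6% (promoter peaks), all past the threshold, and at 31.4% (50 bp) and 52.1% (upper flank), which were not. At 56.6% it lay above unbound promoters at the same distance, past the threshold only with matched GC content (41.9%, Fisher's exact test, p = 4.0e-21). With the stricter motif, at 42.4%, it lay below its flank and past the threshold. Log2 signal differences that had not passed changed sign for small RNA genes (-0.40, nearest gene), collagens (-0.29 to 0.17 without 1 replicate) and chemoreceptors (-0.52 to -0.27 without 1 replicate). Averaged over the replicates, the share of genes with as few peaks as dpl-1 was 1.55% within 10 kb and 2.33% within 40 kb. For unc-119 the averaged share was 94.2% within 10 kb. The E2F share changed sides of the other promoter peaks at 12.5% and 22.2% (meiotic and neuronal, stricter motif), 16.7%, 22.2%, 11.1% and 0% (DREAM, neuronal, histones and chemoreceptors, 50 bp) and 25% (chemoreceptors, 250 bp), none of them past the test. Depth is unknown, so what it limits could not be measured, and a gene without a peak is not shown to be free of DPL-1.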

Other observations

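The tests in this part were chosen only after the data had been seen, except those of repeats and of gene number around dpl-1. Genes of general cell growth outside the fixed lists were bound often. Among 12 added families, 8 had a higher and 4 a lower bound share than other genes. Proteasome genes were bound in 29 of 33 cases (87.9%, replicates 78.8% ± 8.57, SD, n = 2; Fisher's exact test, adjusted p = 8.3e-20 over 12 families), nuclear pore genes in 20 of 26 (76.9%, replicates 76.9% ± 5.44, adjusted p = 4.9e-12) and translation factor genes in 28 of 37 (75.7%, replicates 71.6% ± 1.91, adjusted p = 4.3e-16), led by eef-2 (signal 1164) and eif-3.C (1071). Part of these are peaks of the fixed lists, such as the npp-3 peak shared with top-2. Sm protein and splicing factor genes followed with 22 of 35 (62.9%, replicates 64.3% ± 6.06), RNA polymerase subunits with 12 of 21 (57.1%), respiratory chain genes with 22 of 39 (56.4%, replicates 57.7% ± 1.81), aminoacyl-tRNA synthetases with 17 of 31 (54.8%, replicates 51.6% ± 13.7, SD, n = 2) and mitochondrial ribosomal proteins with 33 of 66 (50%, replicates 47.7% ± 5.36), each with an adjusted p of 8.2e-06 or lower. Cytochrome P450 genes (2.70%, replicates 4.05% ± 1.91, SD, n = 2), C-type lectins (2.08%) and ligand-gated channels (1.1%) were bound less often, and 0 of 54 sperm protein genes had a peak (Fisher's exact test, adjusted p = 0.00037). With the nearest gene only, the 8 higher shares were between 31.8% and 63.6%, with an adjusted p of 0.00075 or lower in Fisher's exact test, and the 4 lower ones passed too (adjusted p = 0.031 or lower). Peaks at the 8 families with a higher share had an E2F motif in 29.1% of cases against 23.6% of other promoter peaks (Fisher's exact test, p = 0.12).

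Summits also stood at small non-coding RNA genes. Of 703 peaks outside promoter windows, 43 (6.12%, 4.46 to 8.15) lay within 100 bp of a tRNA gene, against at most 0.711% over circular shifts, 38 (5.41%) at a snoRNA gene and 7 (0.996%) at an snRNA gene, each with p = 0.001 in a circular permutation test, the smallest possible. The CHR motif, which did not pass over all peaks, was more frequent at 5 of 16 lists than at other promoter peaks. It was found at 86% of chromosome segregation peaks (against 55.8%, Fisher's exact test, adjusted p = 3.5e-05), 88.6% of DNA repair peaks (adjusted p = 0.00070), 84.6% of cell-cycle control peaks (adjusted p = 0.017), 78.6% of DNA replication peaks (adjusted p = 0.017) and all 8 meiotic peaks (adjusted p = 0.037). These comparisons had no match for GC content and no reordered CHR motif as a control. Of the 8 bound meiotic genes, 2 had only peaks that also lay at genes of other lists with a higher bound share. Around the summit the share of the CHR motif was 4.43% in the bin centred 10 bp below and 9.58% in the bin 30 bp below.

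The widest peak interval of each of the 4 ce11 lists lay on egl-5. It spanned 2662 bp with 5 summits in the IDR list (III:7814331-7816992), 2657 bp in replicate 1 and 2623 bp in replicate 2, while the next widest interval of the IDR list, at pri-2, spanned 449 bp. The 8-mer most enriched at summits on chromosomes I, III and V, AGACGCAG, was found on II, IV and X at 15.5% of summits and 1.25% of flanks (exact McNemar p = 3.0e-39).

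The empty region around dpl-1 was weighed against technical explanations, and neither here nor for the E2F motif was a biological explanation tested. Repeats to which reads cannot be placed are argued against, since 98.5% of the 31-mers within 20 kb of dpl-1 occur once in the genome, above the median of 94.6% and the 5th percentile of 74.8% for such windows around genes. A low number of genes was not decided by the count of empty windows. The window holds 11 annotated 5' ends against a median of 13, and 36.0% of windows around genes have as few. Of these 7195 windows, 20 (0.278%) lack a peak in both replicates, so few 5' ends alone seldom left a window empty. Only 51 windows around any gene lack a peak in both, so that share had to be low, and windows of neighbouring genes overlap. Extra copies of the region in the strain, which could raise the control or the local background over the 53.7 kb of replicate 1, remain open, because the lists give no read depth and the control was not analysed here.

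For the E2F motif at summits, base composition as the whole cause is argued against, since windows at the same distance from peak-free genes with matched GC content held the motif in 8.21% of cases, against 24.2% of 2058 promoter summits (Fisher's exact test, p = 1.5e-45). Summits rich in this kind of sequence in any order remain a candidate explanation for the peaks as a whole. The enrichment of the E2F motif over GC-matched windows was 1.04 times that of the reversed motif (95% bootstrap interval 0.792 to 1.37). At DNA replication and chromosome segregation promoters that explanation is argued against. There the E2F motif had an odds ratio of 5.62 (3.63 to 8.78) relative to other promoter peaks and the reversed motif 1.06 (0.546 to 1.91; Fisher's exact test, p = 0.88). These 2 lists were grouped after the E2F motif had passed at both, so its odds ratio there is not independent support. The reversed motif played no part in that choice, and it passed at 0 of 16 lists.

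Ribosomal protein promoters held strong peaks with few E2F motifs (11.6%), a difference that did not pass the correction in the main window. The 8-mer AGACGCAG as the element of these promoters is argued against, as it was found in 5.80% (1.60 to 14.2) of 69 ribosomal protein peaks and in 13.1% of other promoter peaks. General enrichment of highly active promoters in the precipitate may also place peaks there, and 24 of the 69 peaks were among the 500 strongest of 2797. That possibility cannot be told apart from recruitment of DPL-1, because no mock precipitation or unrelated factor was analysed here. The same limit applies to the peaks of the other lists, the added families and the non-coding RNA genes.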
